A study of Arabidopsis thaliana with 12 samples.

How the data were processed

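Total RNA from rosette leaves was hybridised to Affymetrix Arabidopsis arrays, 1 array per sample and 1 channel. Per the labels' protocols, plants were 6 weeks old, grown in soil at 60% humidity and 22 °C under days of 16 h, leaves were frozen in liquid nitrogen, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of total RNA. The submitters' processing notes name MAS5, and no version is given in the sources used here. The deposited table holds log2 values, as the values themselves show: they lie on a log scale with a floor of 0, and after conversion to the linear scale the 2% trimmed mean of each array is close to 500.05, so the authors had scaled each array to a common trimmed mean. Scaling of this kind leaves array medians free to differ, and they ranged from 7.10 to 7.55. MAS5 signals of dim probe sets scatter: the median within-group SD was 1.37 below a mean of 3 and 0.253 above 9.

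Samples were grouped by their titles and genotype labels into Col-0, OE1, OE2 and fls1-3, with 3 arrays each, which the titles call biological replicates. Whether these came from separate plants or pools is not given in the sources used here, so p-values measure the spread between these arrays. Within groups, arrays correlated at r = 0.907 to 0.935 across probe sets, and between groups at 0.885 to 0.937, and no 2 arrays held the same values. The groups are named as the arrays are labelled, since the labels' flavonol descriptions conflict and the level of FLS1 could not check them.

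Gene names come from a probe-gene table of the platform annotation of 2016, with locus names from a table of reference genes of the assembly TAIR10.1, used for names and neighbours only. Of the 22746 probe sets tested, after leaving out 64 control probe sets, 13513 name 1 gene, 503 name several and 8730 are unnamed. Where a gene has several probe sets, the one with the highest mean signal stands for it in lists and named genes. Of 146 such genes, 2 had a call in OE2 and 4 in fls1-3, with the probe sets disagreeing on the call for 1 and 3 of them and in no case on direction.

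The deposited values were used without further normalization or a filter on dim probe sets. Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 1 coefficient per group, giving 8 residual degrees of freedom, and moderated with an intensity trend. Benjamini-Hochberg adjustment ran over the 22746 probe sets of each comparison, with a threshold of 0.05. These choices were made before the data were examined. The comparisons were each line against Col-0, OE1 against OE2, the mean of OE1 and OE2 against fls1-3, the overlap of calls, and 22 gene lists in each line against Col-0. Lists with at least 3 named genes were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over 21 tests. The lists cover flavonol, anthocyanin, phenylpropanoid and glucosinolate metabolism, auxin, jasmonate, salicylic acid, ABA, cold, heat and oxidative stress responses, the clock, photosynthesis, senescence, cuticle and stomata, and markers of other cell types. A pseudocount of 16 was planned in case the values proved linear. As they were already log2, they were used unchanged, as planned for that case, and the pseudocounts tried as alternatives were applied as log2 of the linear signal plus 1, 16 or 64.

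The rule for named genes took, per line against Col-0, the 10 largest rises and the 10 largest falls among probe sets that passed, name 1 gene, reach the median signal in the higher group, and separate all 3 arrays of the line from all 3 Col-0 arrays. Where fewer than 5 passed, it took the 5 with the smallest p, and called members of the lists were named too. Genes named for the comparisons between lines and for the overlap of OE2 and fls1-3 are those that passed there. The other processing choices tried were quantile normalization, centring on array medians, pseudocounts of 1 and 64, a filter at the 40th percentile, leaving out probe sets that can cross-hybridise, fitting only the groups compared, no intensity trend, array quality weights, the replicate number as a block, and leaving out each array. Added after the data were seen were the pseudocount of 16, leaving out the lowest-median arrays of Col-0 and fls1-3, the array median as a covariate, the comparison of Col-0 with the mean of the 3 lines, those of fls1-3 with OE1 and OE2 singly, and the overlap of OE2 with fls1-3. Families of genes were formed from shared symbol stems, also after the data were seen. The stem rule was tried in 2 forms, of which the second is reported, and the first gave an additional GSTU family past the threshold in the preset camera test.

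The method was tested on simulated data with 200 changed probe sets and independent noise. At a simulated log2 change of 1 it recovered 23.0%, 21.0% and 24.4% for OE1, OE2 and fls1-3 against Col-0, and at a change of 2 it recovered 58.4%, 54.8% and 54.2%, over 22746 probe sets and 10 simulations. Median false calls were 6, 6.5 and 6.5. The list test found 50 of 50 lists of 5 probe sets shifted by 2 log2 units in OE2 against Col-0, and 1 of 50 unshifted ones. These lists were drawn at random from probe sets of above-median signal, and every member was shifted. They do not show how the test fares on lists of related genes, on dim genes or on smaller shifts. Unchanged groups were also simulated 100 times with noise as correlated between probe sets as on the arrays. The median count of calls was 0 in every comparison, but rare draws gave many: up to 4319 for OE1, 421 for OE2 and 5380 for fls1-3 against Col-0. Counts at least as large as the observed ones came in 1 draw for OE2 and 3 draws for fls1-3.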

Results

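Gene expression was measured in rosette leaves of 6-week-old plants of Arabidopsis thaliana, a small flowering plant used as a model species. The 12 arrays covered 4 genotypes with 3 arrays each. Col-0 was the wild type, OE1 and OE2 were a pair of lines overexpressing TaFLS, and fls1-3 was a mutant named for FLS1, the gene of the enzyme flavonol synthase, which makes flavonols from dihydroflavonols. The labels give a lowered flavonol content for the arrays labelled OE1 and a raised one for the arrays labelled OE2 and for those labelled fls1-3. These descriptions conflict with each other for lines of the same overexpression, so each group below is the set of arrays with that label. Each array gave 22810 probe-set values, with array medians between 7.10 and 7.55 on the log2 scale and between 0.487% and 1.47% of values at the floor of 0. The number of arrays limits the precision of every comparison.

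FLS1, whose level would check the mutant label, has no probe set naming it in the annotation table used here, so its level was not analysed here. The control transcripts differed between groups. The signal of the GAPDH control at its 3' end exceeded that at its 5' end by 2.27 ± 0.17 log2 units (SD, n = 3) on the arrays labelled OE1, against 1.304 ± 0.10 in Col-0, 1.42 ± 0.25 in OE2 and 1.27 ± 0.39 in fls1-3. The actin control gave 3.24 ± 0.38 in OE1, 2.60 ± 0.18 in Col-0, 2.45 ± 0.12 in OE2 and 2.31 ± 0.29 in fls1-3. The ubiquitin control gave 1.25 ± 0.17 in OE1, 0.59 ± 0.14 in Col-0, 0.66 ± 0.11 in OE2 and 0.25 ± 0.045 in fls1-3. On this control fls1-3 stood lowest, with its highest array at 0.29 and the lowest Col-0 array at 0.44, a difference that was not tested. For each of the 3 controls, the exact two-sided permutation p of OE1 against the other 9 arrays was 0.00455, the smallest that 220 splits allow, and adjusted over the 3 tests it was the same. This contrast was chosen after the values were seen.

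**Figure D1:**
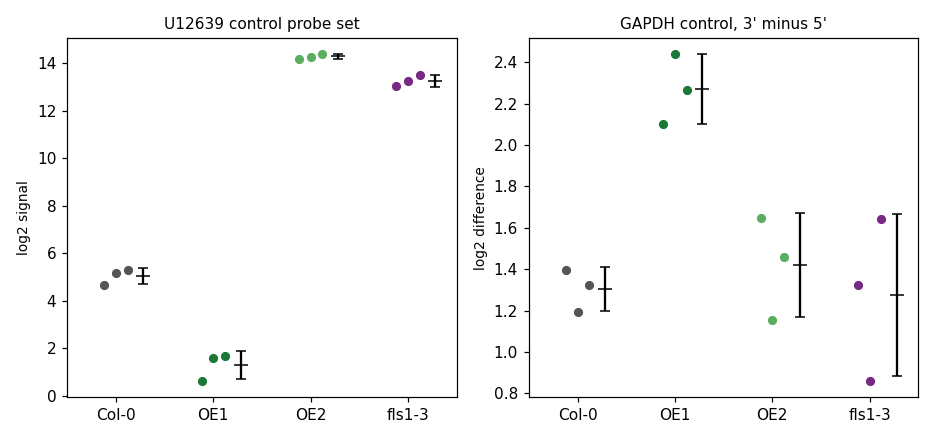
Signal of the U12639 control probe set (left, log2 signal) and of the GAPDH control as the 3' minus the 5' probe set (right, log2 difference) on each array of the 4 groups, with points for arrays and black bars for the mean ± SD of 3 arrays. U12639 averaged 5.05 in Col-0, 1.305 in OE1, 14.28 in OE2 and 13.25 in fls1-3, and the GAPDH difference was highest on the 3 OE1 arrays.

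The first comparison set the arrays labelled OE1 against Col-0. No gene passed the threshold. The lowest adjusted p belonged to QQS, a gene of starch metabolism, at a log2 difference of -2.71 ± 0.34 (SE, n = 3 against 3; adjusted p = 0.0776). Its signal was lower in 3 of 3 OE1 arrays than in every Col-0 array, a separation the naming rule required of the genes it chose. The plastid-encoded gene psaC, for a subunit of photosystem I, stood at 2.86 ± 0.39 (adjusted p = 0.0860), and rpl20, for a plastid ribosomal protein, at 1.302 ± 0.28 (adjusted p = 0.305). ORA47, a transcription factor gene of jasmonate signalling, had a value of -1.82 ± 0.33 (adjusted p = 0.219). AT4G29200 had the largest difference among the named genes, -6.69 ± 1.07 (adjusted p = 0.183), from a Col-0 level of 9.96 to an OE1 level of 3.26 ± 1.76 (SD), in a range where replicate signals scatter. AT2G02160, AT2G30600 and AT3G15630 had values of 0.78, 0.99 and 1.24, and AT3G07090 and AT3G26450 had values of -0.98 and -1.19, none past the threshold. The limma test found 0 probe sets past an adjusted p of 0.05 among 22746, and 2429, or 10.7%, had an unadjusted p under 0.05. That count was close to those of the other lines against Col-0, 2581 in OE2 and 2331 in fls1-3. Under an unadjusted limma p of 0.001 there were fewer in OE1, 65 against 302 in OE2 and 331 in fls1-3. Without Col-0 replicate 3 the count was 22, with QQS, psaC, ORA47, AT3G15630, AT3G07090 and AT3G26450 among them, and without fls1-3 replicate 1 or 2, which enter through the pooled spread, it was 1, with QQS passing. Array quality weights also gave 22 calls, and a pseudocount of 16 or 64 gave 3. With the replicate number as a block, or with only the OE1 and Col-0 arrays fitted, the count was 1.

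The second comparison set the arrays labelled OE2 against Col-0. The transcription factor gene ORA47 fell by 5.02 ± 0.33 on the log2 scale (SE, n = 3 against 3; 32.5-fold; adjusted p = 3.1e-05), and QQS fell by 3.88 ± 0.34 (14.7-fold; adjusted p = 0.000324). STZ, a zinc-finger transcription factor gene of stress responses, fell by 3.09 ± 0.44 (adjusted p = 0.00641). Among the genes that rose, AT5G62360 gained 3.38 ± 0.44 log2 units (10.4-fold; adjusted p = 0.00431) and 4CL8, named for its likeness to 4-coumarate-CoA ligases, gained 2.43 ± 0.34 (5.38-fold; adjusted p = 0.00641). Their Col-0 levels, 5.42 ± 0.48 and 5.52 ± 0.51 (SD), lay below the array medians, so the sizes of these rises are less certain. AT3G15630, AT3G15450 and AT1G52720 rose by 2.31, 1.83 and 1.71, and AT3G14200 fell by 2.44. These 9 genes kept their call when any of the 12 arrays was left out. Each gene named for OE2 had all 3 arrays of the line beyond all 3 Col-0 arrays, which the naming rule required of the genes it chose.

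A further set of genes passed in OE2 but lost the call when at least 1 array was left out. Of these, AT3G23550, MGL, a methionine gamma-lyase gene, AT1G50040, AT2G34930 and AT2G15960 rose by between 1.84 and 2.72. AT4G29200, AT2G18210, AT3G10930, AT1G72920, AT2G15020 and AT3G51750 had log2 changes between -6.64 and -2.23. The -6.64 of AT4G29200 rests on a dim OE2 level of 3.31 ± 2.28 (SD) and the -3.53 of AT2G18210 on one of 3.96 ± 1.66, so both sizes are uncertain. WRKY53, a transcription factor gene of leaf senescence, fell by 2.14 (adjusted p = 0.0113) and lost the call without OE2 replicate 1 or 3. In all, limma called 225 probe sets, 117 higher and 108 lower, of which 181 changed at least 2-fold and 91 name 1 gene. The count was 84 without Col-0 replicate 2, 145 without OE1 replicate 3, and 72, 66 and 91 without OE2 replicates 1, 2 and 3. It was 122 with each array centred on its median, 109 when only the OE2 and Col-0 arrays were fitted, 93 without the intensity trend, 376 with the array median as a covariate, and 671 with array quality weights, of which 315 were higher and 356 lower.

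**Figure D2:**
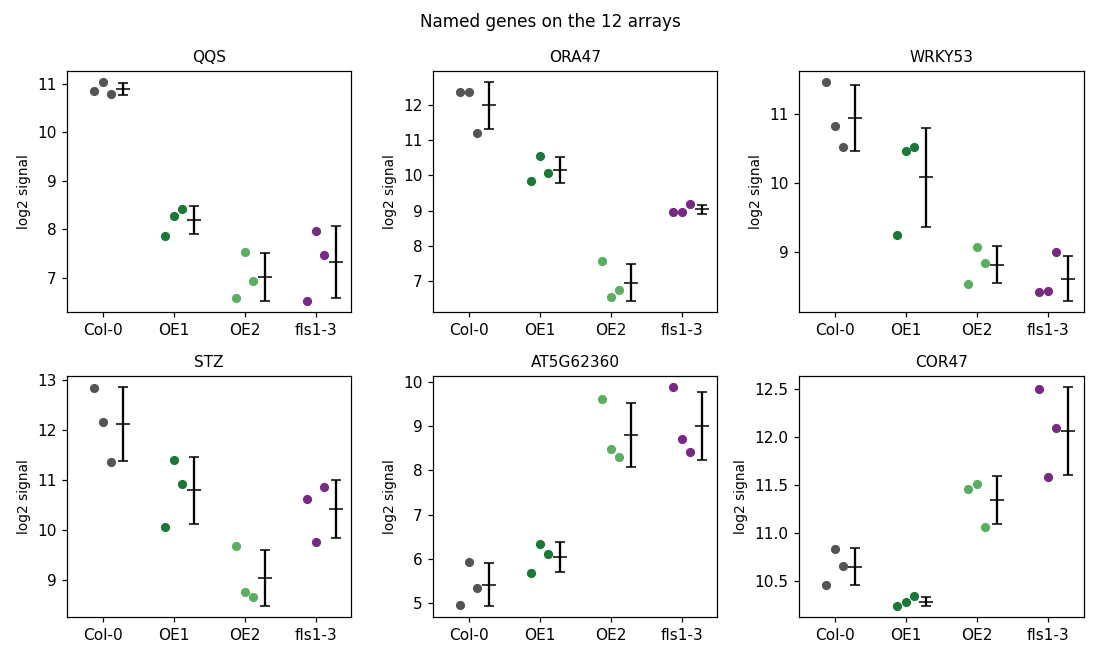
Signal (log2, vertical axis) of QQS, ORA47, WRKY53, STZ, AT5G62360 and COR47 on each array of the 4 groups (horizontal axis), with points for arrays and black bars for the mean ± SD of 3 arrays. QQS averaged 10.89 in Col-0, 8.18 in OE1, 7.01 in OE2 and 7.32 in fls1-3.

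The third comparison set the arrays labelled fls1-3 against Col-0. QQS fell by 3.57 ± 0.34 on the log2 scale (SE, n = 3 against 3; 11.9-fold; adjusted p = 0.000666), ORA47 fell by 2.95 ± 0.33 (7.72-fold; adjusted p = 0.00131) and WRKY53 fell by 2.34 ± 0.34 (adjusted p = 0.00605). ATMRK1 fell by 2.02 ± 0.18 (4.05-fold; adjusted p = 0.000528), while its level in OE1 and OE2 lay within 0.23 log2 units of Col-0. AT5G62360 rose by 3.58 ± 0.44 (adjusted p = 0.00223), AT1G15010 by 3.605 ± 0.55 (adjusted p = 0.00730) and AT5G38710 by 2.65 ± 0.34. COR47, a dehydrin gene of the cold response, rose by 1.41 ± 0.21 (adjusted p = 0.00701). These genes, with 4CL8, AT2G34930 and AT5G05600, which rose by 2.63, 2.55 and 2.50, kept their call when any of the 12 arrays was left out. The sizes for AT5G62360 and 4CL8 rest on the same low Col-0 levels as in OE2. Each gene named for fls1-3 had all 3 arrays of the mutant beyond all 3 Col-0 arrays, which the naming rule required of the genes it chose.

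The cell-wall gene XTH18, a xyloglucan endotransglucosylase, rose by 3.22 ± 0.60 in fls1-3, and AT5G19110, AT4G36010 and AT5G17850 rose by 3.86, 2.63 and 2.50, the first of uncertain size because of a dim Col-0 level of 4.92 ± 0.33 (SD) and an fls1-3 level of 8.78 ± 2.05. The expansin gene EXPA8 fell by 2.34 ± 0.41, and IAGLU, for a glucosyltransferase acting on the auxin indole-3-acetic acid, fell by 1.83 ± 0.37. AT4G29200, AT1G04770, AT5G47610 and AT3G14200 had log2 changes of -5.56, -1.88, -1.76 and -1.70, the first of uncertain size because of a dim fls1-3 level of 4.39 ± 0.86 (SD). Each of these 10 genes lost its call when at least 1 array was left out. In all, limma called 272 probe sets, 184 higher and 88 lower, of which 204 changed at least 2-fold and 122 name 1 gene. The count was 103 without Col-0 replicate 2, and 132 and 144 without fls1-3 replicates 1 and 2. It was 156 with each array centred on its median, 31 when only the fls1-3 and Col-0 arrays were fitted, 103 without the intensity trend, 839 with the array median as a covariate, and 1032 with array quality weights, of which 570 were higher and 462 lower.

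The overexpression lines were then asked for shared changes. No gene was called in both OE1 and OE2 against Col-0, since limma called none in OE1. In OE1, ORA47, QQS and AT3G15630 had differences of the same sign as in OE2. Over the 11373 probe sets of above-median signal, the log2 differences of OE1 and OE2 had a correlation across probe sets, which are not independent replicates, of r = 0.72. Unchanged groups were simulated with every array redrawn, including the Col-0 arrays shared by both lines. Their mean r was 0.35 and the highest 0.95 over 50 simulations. The covariance was 0.155, against a simulated mean of 0.0373 and a highest of 0.268. No gene was called one way in both overexpression lines and the other way in fls1-3. Leaving out Col-0 replicate 3 gave 15 probe sets shared by OE1 and OE2, and leaving out fls1-3 replicate 1 or 2 gave 1.

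Called genes of OE2 and fls1-3 overlapped, a count added after the data were seen. QQS, ORA47, WRKY53, AT4G29200 and AT3G14200 fell in both, and AT5G62360, 4CL8, AT2G34930, AT5G38710 and AT3G15630 rose in both. In all, 117 probe sets were called in the same direction, 69 higher and 48 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.946 higher and 0.418 lower. Unchanged groups simulated in the same way, with every array redrawn, shared 0 in each of 50 simulations. The observed Col-0 arrays were not kept, so this does not show what those arrays alone would give. The log2 differences had r = 0.70 across probe sets (simulated mean 0.41, highest 0.99) and a covariance of 0.156 (simulated mean 0.0434, highest 0.435). The 3 Col-0 arrays cannot be split into parts of at least 2 arrays, so part of the excess may come from the shared controls. The count was 43 without Col-0 replicate 2, 75 without OE1 replicate 3, 42, 42 and 58 without OE2 replicates 1, 2 and 3, and 57 without fls1-3 replicate 2. It was 20 when only the groups compared were fitted, 44 without the intensity trend, 59 with each array centred on its median, 285 with the array median as a covariate and 421 with array quality weights.

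**Figure D3:**
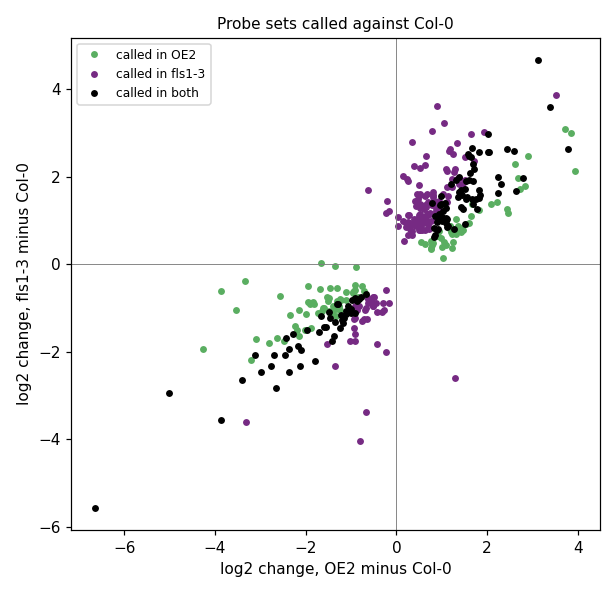
Log2 change against Col-0 in OE2 (horizontal axis) and in fls1-3 (vertical axis) for each probe set called in at least 1 of these comparisons, coloured by where it was called. The 117 called in both lie in the same direction, 69 higher and 48 lower.

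The arrays labelled OE1 and OE2 were compared with each other directly. The OE1 arrays stood apart in the 3' to 5' difference of the control transcripts, by 0.936 for GAPDH. This comparison cannot separate that from the line. ORA47 was higher in OE1 than in OE2 by 3.199 ± 0.33 log2 units (SE, n = 3 against 3; adjusted p = 0.00244), with means of 10.16 ± 0.36 (SD) in OE1 and 6.96 ± 0.53 in OE2. The photosystem I gene psaC was higher in OE1 by 2.72 ± 0.39 (adjusted p = 0.0469). In all, limma called 6 probe sets, 3 higher and 3 lower in OE1, and 2 of them name 1 gene. The ORA47 call held whichever array was left out, and the psaC call was lost when any array other than Col-0 replicate 1 or 3 was left out. The count was 19 without Col-0 replicate 1, 11 without Col-0 replicate 3, and 89 when only the OE1 and OE2 arrays were fitted. Of these, 4 were higher and 15 lower in OE1 without Col-0 replicate 1, 3 and 8 without Col-0 replicate 3, and 19 and 70 with only the OE1 and OE2 arrays. The count moved further to 532 with array quality weights and 211 with the array median as a covariate. It was 57 without the lowest-median arrays of Col-0 and fls1-3, and 13 with the replicate number as a block.

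The mean of the lines labelled OE1 and OE2 was set against fls1-3. ATMRK1 was higher in the overexpression lines by 1.91 ± 0.16 log2 units (SE; adjusted p = 0.000486), with means of 9.34 in OE1, 9.10 in OE2 and 7.31 in fls1-3. COR47 had a difference of -1.25 ± 0.18 (adjusted p = 0.0258) and was highest in fls1-3. AT1G15010, AT5G38710 and AT1G52720 had differences of -3.03, -2.04 and -0.97. The glucosinolate transporter gene GTR1 had a difference of -1.64 ± 0.20 (adjusted p = 0.0107), and psaC one of 2.25 ± 0.33. Of the 34 probe sets limma called, 6 were higher and 28 lower in the overexpression lines, and 15 name 1 gene. With array quality weights most calls lay the other way, 1537 higher and 1063 lower. Taken singly, fls1-3 had 126 calls against OE1 and 5 against OE2, and psaC averaged 9.58 in OE1, 6.86 in OE2 and 5.97 in fls1-3. The higher 3' to 5' difference of the OE1 arrays enters each comparison with OE1 and cannot be told apart from the line. Of the 15 named genes, only ATMRK1 kept its call with any array left out. The count was 125 without Col-0 replicate 1, 8 without Col-0 replicate 2, 15 and 7 without OE1 replicates 1 and 3, 8 and 4 without OE2 replicates 2 and 3, and 4, 11 and 6 without fls1-3 replicates 1, 2 and 3.

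Gene lists written in advance were read in each line against Col-0. Of their 345 genes, 44 have a named probe set, and 7 of the 22 lists hold at least 3 such genes. In the cold regulon, COR47 rose in fls1-3 and the other 3 members did not pass. The list's 4 members were shifted upward in OE2, with a median log2 difference of 0.73 and an adjusted p of 0.0240 by camera. In fls1-3 the median was 0.93 and the adjusted p 0.00199. With an estimated correlation between genes these were adjusted p = 0.419 and adjusted p = 0.373. LTI30, another dehydrin gene, had values of 1.77 in OE2 and 2.55 in fls1-3 without passing. Adjusted over the list alone, 3 members passed in OE2 and 2 in fls1-3. Without Col-0 replicate 1 the adjusted p was 0.299 in both lines, and without OE2 replicate 1 or 2 it was 0.0628 or 0.0978 in OE2. Without any other single array it ranged up to 0.0472 in OE2 and 0.00405 in fls1-3. All 4 members were higher in both lines under each scaling tried. With array quality weights, and without the lowest-median arrays of Col-0 and fls1-3, 0 list shifts passed, so the shift of this list was lost.

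None of the 5 named members of the flavonol list, of 23 genes, passed in any line. UGT78D2, a flavonol glycosylation gene, had log2 differences of 0.12 in OE1, -0.18 in OE2 and -0.58 in fls1-3, of which the first changed sign when the arrays were centred on their medians, and the list had a median of 0.33 in OE1 and adjusted p of 0.573, 0.834 and 0.834 in the same order. DFR, which makes leucoanthocyanidins in anthocyanin synthesis, had values of 1.1004, 1.87 and -0.18, and no member of the anthocyanin and proanthocyanidin list was called. The auxin response list had its lowest adjusted p in OE2, 0.0687, where IAA29 stood at 1.32. In the guard cell and stomatal lineage list, STOMAGEN had values of 1.204, 0.45 and -0.30, and no member passed. STZ of the oxidative stress list fell in OE2, and the other 2 named members did not pass. The 3 named glucosinolate genes did not pass either.

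The remaining lists have at most 2 named genes. WRKY53 fell in OE2 and fls1-3 and is the 1 named gene of the senescence and dark induced list. Nothing was called in any line among HCT and CCR2 of general phenylpropanoid and lignin, PDF1.2 and THI2.1 of jasmonate and wound response, LHCB4.1 and RCA of photosynthesis, GI of the circadian clock, SAG101 of salicylic acid defence, WSD1 of cuticle and wax, or AT1G53540 and ATHSP22.0 of heat shock. The cell type markers EXPA7 for root, SWEET11 for vasculature and TRY for trichomes were not called. The lists for ABA and drought response, auxin transport, dividing cells, and flowering and floral organs have 0 named genes. Adjusted over the list alone, 2 auxin response and 2 oxidative stress genes passed in OE2, with 1 of senescence and 1 trichome marker, 1 oxidative stress and 1 senescence gene in fls1-3, and 1 oxidative stress, 1 senescence and 1 vasculature gene in OE1. The senescence, trichome and vasculature lists have 1 named gene each, so for them this is only an unadjusted limma p under 0.05. In OE1 against Col-0, 10.7% of all probe sets reached that.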

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

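The tests of explanations and the counts over other splits of the arrays were chosen after the results were seen, as were the comparisons of fls1-3 with OE1 and OE2 singly and the overlap of OE2 with fls1-3, while the other comparisons were planned.

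The control probe set U12639, which is outside the gene comparisons, had a mean log2 signal of 14.28 ± 0.10 (SD, n = 3) on the arrays labelled OE2 and 13.25 ± 0.23 on those labelled fls1-3, far above Col-0 at 5.05 ± 0.33 and OE1 at 1.305 ± 0.59. What this probe set detects is not given in the sources used here. A general difference in control hybridisation is argued against by the other 63 control probe sets, whose group means spread over at most 1.32 log2 units. An exchange of the labels of OE1 and fls1-3 may explain both this signal and the conflicting flavonol descriptions, but a sequence carried by OE2 and by the mutant material, and not detected in OE1, would give the same values, so these cannot be told apart without the target of the probe set. The difference of 11.95 log2 units between fls1-3 and OE1 has no exact size, because the OE1 signal lies under 3, where signals scatter with a median SD of 1.37, and shows only that fls1-3 is far higher. No array was regrouped, and no biological explanation was tested.

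Differences between the lines passed direct tests. OE1 and OE2 differed in 6 probe sets, among them ORA47 by 3.199 and psaC by 2.72. Each comparison with OE1 also holds the difference in RNA quality of the OE1 arrays, which cannot be told apart from the line. In the 10 splits of these 6 arrays the other splits gave at most 0 calls, and 1 split, the real one, reached 6, but 10 splits are too few for a share under 0.05. The mean of OE1 and OE2 differed from fls1-3 in 34 probe sets, while fls1-3 alone had 126 calls against OE1 and 5 against OE2. In 100 of the 840 splits of these 9 arrays, 2 gave at least 34, the real one included, and the highest other gave 81. In this comparison, unchanged groups simulated with correlated noise gave at least 34 calls in 1 of 100 draws, with up to 4364 in a draw. The share of splits was not adjusted over the counts tested, so chance is not excluded. What the split with 81 corresponds to was not tested. The differences of single genes were 1.91 for ATMRK1, 2.25 for psaC, -1.25 for COR47, -3.03 for AT1G15010, -2.04 for AT5G38710 and -0.97 for AT1G52720.

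The arrays labelled OE1 had 0 calls against Col-0 where OE2 had 225 and fls1-3 had 272, although the direct test of OE1 against OE2 called only 6, so a difference in size between OE1 and OE2 is shown for those probe sets alone. ORA47, 1 of them, was also lower in all 3 OE1 arrays than in every Col-0 array, by 1.82, without passing. The naming rule chose it for that separation among other conditions. The spread between the OE1 arrays, with a median SD of 0.360 against 0.267 in OE2 and 0.420 in fls1-3, decides nothing, because the model pools the spread over all 4 groups. Col-0 replicate 3 as the whole cause is argued against, since leaving it out gave 22 calls in OE1 and 303 in OE2. The RNA quality of the OE1 arrays, whose GAPDH 3' to 5' difference was 0.936 above that of the other arrays, may contribute and cannot be told apart from the line, because all 3 OE1 arrays share it. A weaker effect of the line itself stays open and untested. The exchange of the labels of OE1 and fls1-3, raised above for U12639, stays open here too. The arrays labelled fls1-3 had 5 calls against OE2 and 126 against OE1. With such an exchange, the 0 calls would not belong to an overexpression line.

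For the comparisons against Col-0, 10 splits of 6 arrays are too few for a share under 0.05. All 10 splits reached the 0 calls of OE1, with 0 as the highest other, which any split must, so this count says nothing. For OE2, 1 split reached the real 225, and the highest other was 0. For fls1-3, 1 split reached the real 272, and the highest other was 5. In 100 drawn splits of all 12 arrays into 4 groups, 1, the real one, reached the 117 probe sets shared by OE2 and fls1-3. The highest other was 1. Splits that mix the groups count the differences between groups as spread, and both comparisons of a split share its Col-0 arrays. The overlap was also picked after the data were seen, so chance is not excluded for that count. All 100 reached the 0 shared by OE1 and OE2 (highest other 1) and the 0 in opposite directions in fls1-3 (highest other 0), which is likewise fixed in advance for a count of 0 and says nothing. For the 2 gene list shifts, 20 of the 100 gave at least as many, with 5 as the highest other, so chance cannot be excluded for the shift of the cold regulon.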

How the results depend on the processing

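The tests with a pseudocount of 16, without the 2 lowest-median arrays and with the array median as a covariate were chosen after the data were seen, as were the overlap of OE2 with fls1-3 and the comparison of Col-0 with the 3 lines. The check of the FLS1 level was not run, as no probe set names it. Counts of calls moved with the model of the spread and with single arrays, and the cause was not tested. Under the 13 other settings and the 12 omissions of 1 array, no sign changed among the genes chosen by the naming rule or called, 10 in OE1, 21 in OE2 and 21 in fls1-3 against Col-0, 2 in OE1 against OE2, 15 in the mean of OE1 and OE2 against fls1-3, and 4 in Col-0 against the 3 lines, where fitting only the groups compared does not apply. For genes named against Col-0 this says little. Their arrays did not overlap with those of Col-0, which the naming rule required, so leaving out 1 array could not reverse the sign. All 5 list members whose uncalled values are printed changed sign in at least 1 line, for causes not tested. In OE1, UGT78D2 was -0.045 centred, -0.0715 without the lowest-median arrays, -0.0692 with the covariate and -0.0715 to 0.276 with 1 array left out, DFR was -0.83 with the covariate, and LTI30 was 0.343 with weights and -0.3695 to 0.467 with 1 array left out. In OE2, STOMAGEN was -0.346 without the lowest-median arrays, -0.0985 with the covariate and -0.346 to 0.893 with 1 array left out. In fls1-3, leaving out 1 array gave -1.19 to 0.650 for DFR, -0.1765 to 0.704 for IAA29 and -1.09 to 0.148 for STOMAGEN. LTI30 passed in fls1-3 with weights, with the covariate and without fls1-3 replicate 3. The other list members that did not pass were not followed. Array quality weights gave 22 calls in OE1, 671 in OE2 and 1032 in fls1-3 against Col-0, 532 for OE1 against OE2, 2600 for the mean of OE1 and OE2 against fls1-3, 15 shared by OE1 and OE2, and 0 list shifts. Of the 2600, 1537 were higher and 1063 lower, against 6 and 28 as reported, of the 671, 315 and 356, against 117 and 108, and of the 1032, 570 and 462, against 184 and 88. Fitting only the groups compared gave 1, 109, 31, 89, 87, 1 and 3 in the same order, with 19 higher and 70 lower among the 89. Without the intensity trend, OE2 had 93, fls1-3 103 and the mean of OE1 and OE2 against fls1-3 5. Centring on the array median gave 122 in OE2, 156 in fls1-3 and 3 list shifts. Quantile normalization gave 10 for OE1 against OE2, 3 higher and 7 lower against 3 and 3 as reported, and 3 list shifts. The filter at the 40th percentile gave 3 list shifts. Pseudocounts of 16 and 64 each gave 3 calls in OE1 and 2 shared by OE1 and OE2. The array median as a covariate gave 376 in OE2, 839 in fls1-3, 211 for OE1 against OE2, of which 80 were higher and 131 lower, and 95 for the mean of OE1 and OE2 against fls1-3. Without the lowest-median arrays of Col-0 and fls1-3 these last 2 were 57, of which 10 were higher and 47 lower, and 6, and 0 list shifts passed.

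The replicate number as a block gave 1 call in OE1, 13 for OE1 against OE2, 1 shared by OE1 and OE2, and 3 list shifts. It moved the counts of OE2 to 166, of fls1-3 to 219 and of the mean of OE1 and OE2 against fls1-3 to 39, all within 1.5 times. Whether the numbers pair the arrays was not settled: of 18 pairs of arrays with the same number, 5 had deviations correlated above 0.1, and r ranged from -0.72 to 0.75. Pairs with different numbers were not read for comparison, so a shared batch is not excluded.

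Leaving out 1 array at a time gave 0 to 22 calls in OE1 (22 without Col-0 replicate 3, 1 without fls1-3 replicate 1 or 2), 66 to 303 in OE2 (84 without Col-0 replicate 2, 145 without OE1 replicate 3, 72, 66 and 91 without OE2 replicates 1, 2 and 3), 103 to 369 in fls1-3 (103 without Col-0 replicate 2, 132 and 144 without fls1-3 replicates 1 and 2), and 4 to 19 for OE1 against OE2 (19 and 11 without Col-0 replicates 1 and 3). The mean of OE1 and OE2 against fls1-3 had 4 to 125, with 125 and 8 without Col-0 replicates 1 and 2, 15 and 7 without OE1 replicates 1 and 3, 8 and 4 without OE2 replicates 2 and 3, and 4, 11 and 6 without fls1-3 replicates 1, 2 and 3. Leaving out 1 array gave 0 to 15 shared by OE1 and OE2 (15 without Col-0 replicate 3, 1 without fls1-3 replicate 1 or 2), 0 to 0 in opposite directions, and 0 to 3 list shifts: 0 without Col-0 replicate 1, 3 without Col-0 replicate 2 or OE1 replicate 1 or 2, and 1 without OE2 replicate 1 or 2. The overlap of OE2 and fls1-3 ranged from 42 to 135 (43 without Col-0 replicate 2, 75 without OE1 replicate 3, 42, 42 and 58 without OE2 replicates 1, 2 and 3, 57 without fls1-3 replicate 2). Its 117 became 20 with only the groups compared, 44 without the trend, 59 centred, 285 with the covariate and 421 with weights. Of the 252 values of 21 named genes in OE2, 203 kept their call and 49 lost it, and of the 252 in fls1-3, 205 kept it and 47 lost it. Of the 120 in OE1, 8 gained a call. Under the other 13 settings 244 of 271 kept it in OE2 and 236 of 271 in fls1-3, and 17 of 129 gained one in OE1. Scaling set the median of all probe sets: in OE1 against Col-0 it was 0.106 as deposited, 0.00725 after quantile normalization and -0.0592 after centring, and in OE2 0.0833, 0.00733 and -0.0698. Dim signals limit what can be called, since probe sets with means of 3 to 5 had a median SD of 1.29.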

Other observations

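The comparison of Col-0 with the 3 lines, the gene families, the neighbours of ATMRK1, the readings without Col-0 arrays, the principal component and the tests of explanations were chosen after the data were seen, while the calls of each line against Col-0 were planned.

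Genes of the plastid genome and of autophagy stood apart in OE1 as groups at the preset correlation of camera, with adjusted p of 0.000362 for ATG and 0.00574 for plastid-encoded genes, though no single member was called. With an estimated correlation these were adjusted p = 0.690 and adjusted p = 0.964, and the OE1 arrays also had the higher 3' to 5' difference of control transcripts, 0.936 for GAPDH. All 8 ATG genes, which encode proteins of autophagy, were lower than in Col-0, with a median log2 difference of -0.46, -0.56 after quantile normalization and -0.63 after centring on array medians. The test covered 45 families named by a shared symbol stem, in 135 tests. Of 69 plastid-encoded genes, 51 were higher in OE1 as deposited and 38 after centring, with medians of 0.23 and 0.0662, while the median of all probe sets was 0.106 as deposited and -0.0592 after centring. The families rpl and rps, whose members are all plastid-encoded and so are no separate evidence, had 7 of 7 and 8 of 8 higher under each scaling.

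ATMRK1 fell in fls1-3 and was called in neither overexpression line. Its 10 nearest named neighbours had 0 limma calls in fls1-3, with log2 differences from -1.56 to 2.58. Both ends of this range come from dim probe sets, those of AT3G63095 and AT3G63230, with SE of 0.77 and 1.02, so the absence of calls does not show that the neighbours were unchanged. Unnamed probe sets have no position in the sources used here, so neighbours among them were not read. The sign of a change called against Col-0 can be read again without any Col-0 array. The counts of calls in these readings are not free of Col-0, because the model pools the spread over all 4 groups. Probe sets called against Col-0 were also picked in part for a low pooled spread. Of the 225 probe sets called in OE2, 193, or 85.8%, had the same sign in fls1-3 against OE1, a comparison that shares no array, against 46.6% of all probe sets, and 33 were called there. Of the 272 called in fls1-3, 249, or 91.5%, had the same sign in OE2 against OE1, against 60.8% of all probe sets, and 4 were called. The OE1 arrays are the reference in both readings, and all 3 stand apart in the 3' to 5' difference of the GAPDH control, by 0.936.

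Col-0 stood apart from the 3 lines in 186 probe sets, 81 higher and 105 lower in Col-0. The count was 57 without the intensity trend, 88 with each array centred on its median, 122 with the replicate number as a block, 333 with the array median as a covariate and 486 with array quality weights. QQS was higher in Col-0 by 3.39 ± 0.28 and ORA47 by 3.26 ± 0.27, while 4CL8 had a difference of -2.21 and IRX15-L, for a protein of xylan synthesis, one of -1.61. In 100 drawn splits of the 12 arrays, 3 gave at least 186, the real one included, and the highest other gave 1731. Other splits thus gave counts at least as large, and what sets those splits apart was not tested.

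A single Col-0 array as the whole cause of this pattern is argued against, since at least 37 of the 186 calls were kept when any 1 Col-0 array was left out, though the count was 38 without Col-0 replicate 2, 97 without Col-0 replicate 1, 105 without OE1 replicate 3, 103, 106 and 100 without OE2 replicates 1, 2 and 3, and 106 without fls1-3 replicate 2. The deposited scaling as the whole cause is argued against as well, since 84 calls were kept with each array centred on its median. A difference in how Col-0 plants were grown or harvested may also separate them from all 3 lines, and it cannot be separated from the genotype here because each group is 1 genotype. The first principal component, with 20.4% of the variance, followed the array median (r = 0.99, rho = 0.99, permutation p = 1e-05 each, the smallest 100000 resamples can give, n = 12; r = 0.98 without the 2 arrays farthest from the median).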
